A study of Mus musculus with 2 samples.

How the data were processed

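H3K4me1, the monomethylated form of lysine 4 of histone H3, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse regulatory T cells. Per the labels, the 2 libraries were technical replicates 1 and 2 of 1 biological replicate, with the material labelled adult, male and 4 months old. No second condition, antibody or control library was analysed here.

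Each library had 1 deposited table of whole-number counts, unscaled, per numbered row. Per the deposited file descriptions, each table is a quantification called enrichment, made from that library's own mm10 alignment and from 1 further file common to both libraries. That common file was not used here. The tables hold a running row number from 1 to 33643 and a count, with no coordinates, gene identifiers or region lengths. Rows are called regions below, and equal row numbers in the 2 tables were taken to stand for the same region. The aligner, the counting tool, the treatment of duplicate reads and any subtraction of a control are not given in the sources used here. The values were all whole numbers of at least 0, and the 2 libraries had different totals. The total of a table counts reads in its regions and not the reads of the whole library, whose depth is not given in the sources used here.

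The analysis was planned, and its gene lists and rule for named items fixed, before the data were examined. Of the 5 planned results, 3 need gene names or positions (the H3K4me1 level over 16 gene and marker lists, the share of list members with a region, and the position of regions relative to genes). These 3 were not computed, because rows were given no gene or position, and no gene was assigned from a row's place. For the same reason the parts of the naming rule about Foxp3 and the lists were not applied. The part that names the 10 regions with the highest count was applied. The part that names regions differing between the libraries gave none, because no region passed the test.

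The agreement of the libraries was measured across regions as Pearson's r of log2(count + 1), after replicate 2 was scaled to the total of replicate 1, and as Spearman's rho. These correlations are across regions, which are not independent replicates, so no p-value was attached. The relative spread was the squared departure of a region's replicate 1 count from its expected share of the summed count, divided by its binomial variance and averaged over regions. It is 1 for independent reads. It was compared with 10000 random splits of the summed counts, and the correlations with 1000 such splits. Each region was tested with a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test covers counting error and compares 2 libraries, not conditions. With 1 biological replicate no model of the spread between animals was fitted.

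The between-region coefficient of variation beyond counting was the square root of the covariance of the 2 libraries over the product of their means. Breaks in the row order were found by circular binary segmentation of log2(summed count + 1), with at least 25 regions per segment and a difference of at least 7 standard errors between neighbours. The segmentation and its settings were chosen after the data were seen, as was the count of 200 above which regions were set apart. Intervals of means and ratios are 95% bootstrap intervals over regions, except that of the relative spread in the regions above 200 counts. That interval uses chi-square quantiles, which assumes near-normal departures. Intervals of single counts are exact Poisson intervals and those of shares are Wilson intervals. These, and the limit of 3 counts that a count of 0 allows, cover counting error only.

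The scripts were tested on simulated libraries drawn from the 33643 summed counts. With 200 regions changed 2-fold between the libraries the test recovered 0, with 200 changed 4-fold it recovered 35 (17.5%), and with 200 changed 8-fold it recovered 107 (53.5%), with 2 false calls in the last case. With no region changed it made 0 false calls. The segmentation was instead tested on independent simulated rows around a common level, with a lowered stretch longer than any reported below and a lower end. It found 3 of 3 breaks to within 1 row, and 0 where none was set. Shorter stretches and related neighbouring rows were not simulated. Alternatives were a pseudocount of 0.1, median-ratio scaling, low-count filters, each library alone, and leaving out the regions above 200 counts. Python 3.11.15, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.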

Results

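H3K4me1 ChIP-seq was performed on regulatory T cells, the CD4 T cell lineage defined by the transcription factor Foxp3 and known for restraining immune responses. H3K4me1 is a histone mark found at enhancers and at the flanks of active promoters. Per the labels, the cells came from the Foxp3CreERT2 x Rosa26YFP strain, in which Foxp3-expressing cells carry a drug-inducible Cre recombinase and can be marked by a yellow fluorescent reporter. The 2 libraries were technical replicates of 1 biological replicate, so the design held 1 group and no contrast between conditions. The comparisons it allows are between regions within these cells and between the 2 libraries. Nothing here measures the spread between animals.

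Both libraries gave reads over nearly all of the 33643 regions counted. The regions of technical replicate 1 held 301180 counts and those of technical replicate 2 held 281127, a ratio of 1.07. At least 1 read was present in both libraries at 32836 regions (97.6%). The median region had 8 counts in replicate 1 and 7 in replicate 2, with exact 95% Poisson intervals of 3.45 to 15.8 and 2.81 to 14.4. The level of a single region was therefore known only coarsely. No count was recorded at 404 regions (1.20%) in replicate 1 and at 464 (1.38%) in replicate 2, and 61 regions had none in either library. A count of 0 allows up to 3 counts, so at the 61 regions without a read in either library H3K4me1 was not detected at this depth, which does not show that it was absent. Because region lengths were not used, a high count may belong to a long region as well as to a strongly marked one.

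**Figure D1:**
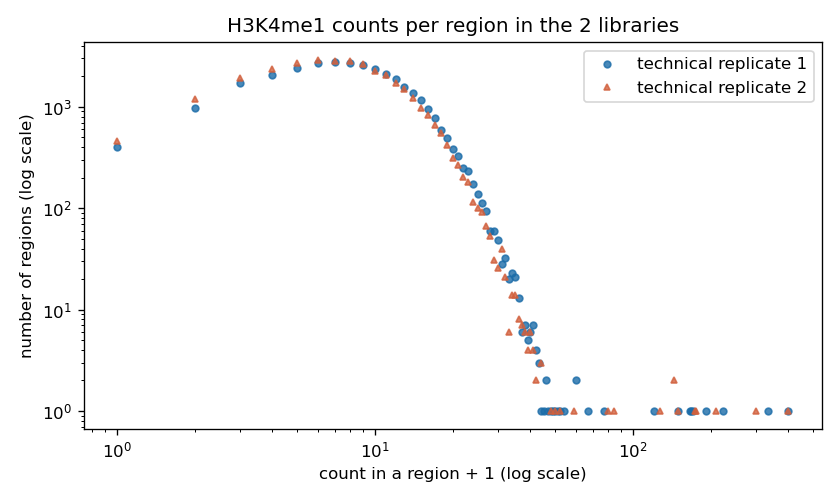
Number of regions (vertical axis, log scale) at each count plus 1 (horizontal axis, log scale) in technical replicate 1 (circles) and technical replicate 2 (triangles). Most regions lie near the medians of 8 and 7 counts, and a few isolated points reach 399 and 397 counts.

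The level of H3K4me1 counts differed between regions by more than counting error. After counting noise was removed, the between-region coefficient of variation was 68.2% (95% interval 58.5 to 78.6%), and 55.0% (54.2 to 55.8%) without the 9 regions whose summed count was above 200. Region lengths and a control library were not used, so this variation of counts need not be variation of the mark. The middle 50% of regions had summed counts of 10 to 23, and the top 1% of regions (336) held 3.98% of all counts. 

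A group of 9 regions stood apart at the top. Their summed counts ran from 245 to 796, which was 16.3 to 53.1 times the median of 15, while the next region had 159. Together they held 3725 counts, 0.640% of the total (Wilson 95% interval 0.620 to 0.661%). The highest, row 6635, had 399 counts in replicate 1 and 397 in replicate 2, a sum of 796 (exact Poisson 95% interval 742 to 853). Row 18076 followed with 333 and 298 counts, and row 4941 with 223 and 209. The other regions among the highest 10 were rows 12073, 8283, 1419, 26163, 13152, 5856 and 15676, whose sums fell from 365 to 159. In each of these 10 regions the share of counts in replicate 1, between 47.8% and 53.6%, had a Wilson 95% interval that held the share over all regions, 51.7%. No gene or position is given for these rows.

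The comparison of the 2 libraries asks whether the technical replicates gave the same profile. Across regions, Pearson's r of log2(count + 1) was 0.677 and Spearman's rho was 0.688. On unlogged counts r was 0.806, and 0.728 without the 9 regions above 200 counts. Random splits of the summed counts into 2 libraries of these sizes gave a median r of 0.670 on the log2 scale (95% range 0.666 to 0.675 over 1000 splits), so the libraries correlated slightly more closely than such splits. The SD of the log2 difference between the libraries was 0.734, just under the 95% range of the splits (0.736 to 0.749).

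No region passed the test for a difference between the libraries. The two-sided exact binomial test over 33582 regions with reads gave 0 regions at an adjusted p under 0.05 (lowest adjusted p = 1), and 1039 (3.09%) at an unadjusted p under 0.05. Random splits gave a median of 1108.5 such regions (range 1039 to 1188 over 100 splits). The lowest unadjusted p of this exact test was 0.000329. In simulation this test recovered 53.5% of 8-fold and 17.5% of 4-fold differences and none of 200 2-fold ones, so most differences of 4-fold or less at single regions of ordinary count would have been missed. Over all regions together the comparison is far more precise. The relative spread of the libraries was 0.976 of counting noise, below the 95% range of 0.986 to 1.01 in 10000 random splits. The 2 libraries thus differed by less than the sampling noise. They were counted as 1 sample because the labels give them as technical replicates of 1 biological replicate.

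**Figure D2:**
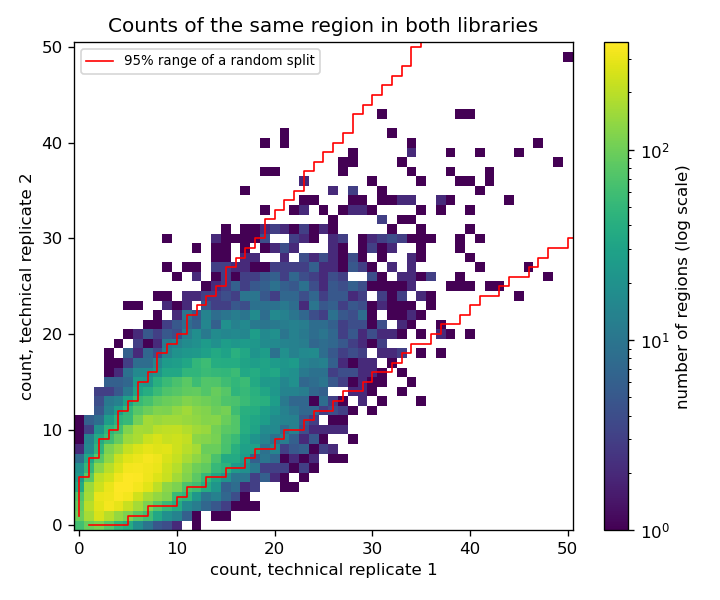
Counts of each region in technical replicate 1 (horizontal axis) against technical replicate 2 (vertical axis), coloured by the number of regions at each pair of counts (log scale), with red lines for the 95% range of a random split of the summed count. Of the 33582 regions with reads, 32812 (97.7%) lie within that range, and 15 regions above 50 counts in either library are outside the axes. The limits of the range are whole counts, so a random split also places more than 95% of regions within it.

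Regions next to each other in the deposited order had related counts, and the order fell into 2 long blocks. The first block, rows 1 to 20101, had a mean summed count of 19.0 (95% interval 18.8 to 19.2), and the second, rows 20634 to 33509, a mean of 15.3 (15.1 to 15.4). The second was 0.804 times the first (0.792 to 0.816), with the same ratio of 0.804 in each library. These means leave out 4 stretches of consecutive rows with far lower counts. Rows 20102 to 20633, between the blocks, had a mean of 7.65 (7.30 to 8.06, 532 regions), which was 0.403 times the first block (0.380 to 0.424) and 0.501 times the second (0.475 to 0.529). Rows 33510 to 33643, at the end of the tables, had a mean of 6.60 (5.70 to 7.53, 134 regions), 0.432 times the second block (0.379 to 0.493). Within the first block, rows 11987 to 12019 had a mean of 8.0 (6.27 to 9.88, 33 regions), 0.421 times its level (0.331 to 0.518). Within the second, rows 25859 to 25938 had a mean of 7.08 (5.86 to 8.38, 80 regions), 0.463 times its level (0.383 to 0.550). The 4 stretches together made up 779 regions, 2.32% of all. The stretches and blocks were delimited from the same counts after these were seen, so the intervals leave out the error of choosing the borders. They also treat regions as independent, although neighbouring ones had related counts, and so may be too narrow.

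**Figure D3:**
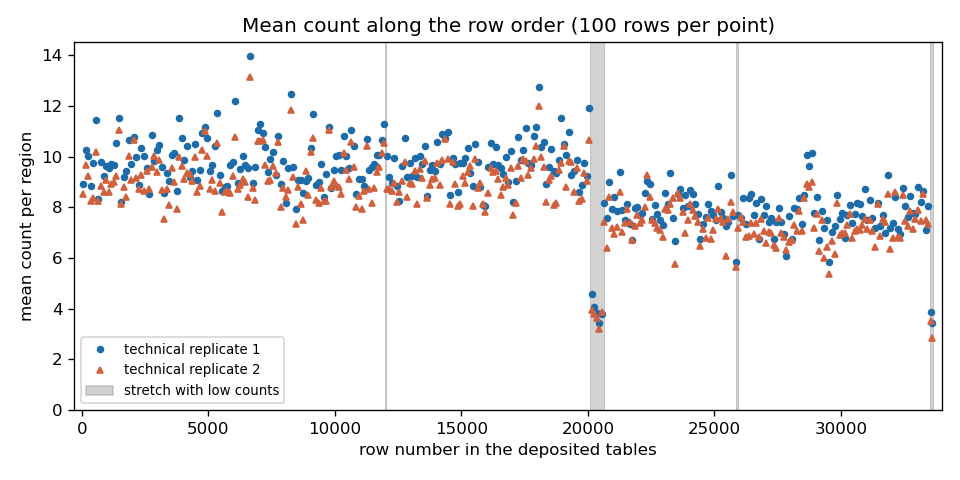
Mean count per region (vertical axis) in successive groups of 100 rows along the deposited row order (horizontal axis) for technical replicate 1 (circles) and technical replicate 2 (triangles), with the 4 stretches of low counts shaded. Both libraries fall in the stretches at rows 20102 and 33510, the 33-region stretch at row 11987 is shorter than 1 point and shows no fall at this scale, and the second block lies at 0.804 times the level of the first.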

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

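The correlation of the technical replicates depended on how low counts were treated. Pearson's r of log2 counts was 0.607 with a pseudocount of 0.1, where the cause was not tested, and 0.474 without the lower 25% of regions, which narrows the range of levels by construction, against 0.677 as reported. Median-ratio scaling left it at 0.677, and leaving out the regions above 200 counts at 0.674. The relative spread was 0.976 under median-ratio scaling and without the regions above 200 counts, 0.972 without regions under 10 summed counts and 0.971 without the lower 25%. Each was below the 95% range of its own random splits. The count of regions differing between the libraries by the exact binomial test was 0 under both alternatives, with 1048 regions (median-ratio scaling) and 865 (regions under 10 left out) at an unadjusted p under 0.05. The ratio of the stretch at row 20102 moved from 0.403 against the first block to 0.501 against the second. In either library alone the ratios of the 4 stretches lay between 0.400 and 0.505. Of 4 other segmentation settings, 3 covered at least 90% of each stretch. A minimum of 50 rows missed the stretch at row 11987, which has 33 regions and could not be returned at that setting. A minimum of 6 standard errors gave 9 breaks in place of 7. These alternatives, except the pseudocount, scaling and low-count filters for r and for the binomial test, were chosen after seeing the data. Alternatives that need positions or genes (overlap, autosomes, promoter width, gene assignment, random lists) were not run. No paired analysis was possible because the labels give 1 group. Depth limits the precision of single regions, whose median counts were 8 and 7.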

Other observations

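The relative spread of the libraries was planned before the data were examined, and the other tests in this part were chosen after the pattern they address was seen. Those on the 90th percentiles, on the negative binomial fit and on the spread of the 9 highest regions had their predictions written before their own values were seen. The labels give 1 group, so no comparison of conditions bears on any of the patterns.

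The 4 stretches of consecutive rows with low counts are the pattern a reader would most want to trace back to the genome. Their weakest border had a statistic of 8.04, and the highest of 100 random orders of the rows was 5.84. Only borders of at least 7 standard errors were kept, so each kept border had to exceed 5.84. The random orders all stayed under this limit of 7, so none would have given a border. The deposited order gave 7 borders, with statistics up to 32.7. That argues against a chance order of the rows as a whole. Random orders hold no relation between neighbours, so single short stretches are not decided by this comparison. Over the whole order, neighbouring rows had related counts (correlation 0.0898 with the next row after the mean of each segment was removed, 95% range of shuffles -0.0105 to 0.0112). A fault in 1 library is argued against, because the highest ratio to a neighbouring block in either library was 0.505, and a mixture of near-empty and ordinary regions is argued against for the stretches at rows 11987, 20102 and 33510, where the ratio of 90th percentiles reached at most 0.464. Its upper 95% limits lay under the bound of 0.75 set for this. They were 0.536 at row 20102 and 0.541 at row 33510, but 0.6875 at row 11987, which has only 33 regions. That mixture stays open for the stretch at row 25859 (ratio 0.468, 95% interval 0.348 to 0.754). The 90th percentiles bear on such a mixture only as the whole cause. Regions without a count made up 5.22% at row 33510 and 6.25% at row 25859, against 0.258% in the second block. At row 20102 they made up 1.13%, and at row 11987 there were 0. A partial share of near-empty regions in the fall was not tested. A candidate explanation is regions present in fewer copies, such as a chromosome that male cells carry once; for the stretch at row 20102 a halving alone cannot be told apart from a larger fall, since it borders both blocks and was 0.501 times the second and 0.403 times the first. The 2 shortest stretches pooled gave 0.451 (0.388 to 0.522), which holds 0.5, while at row 33510 the ratio of 0.432 lay narrowly below it (upper limit 0.493, but 0.516 in replicate 1 alone). These intervals treat rows as independent and may be too narrow, so the margin at row 33510 does not decide against a halving. Fewer copies together with shorter or weaker regions remains open and was not tested, since no row was assigned to a chromosome.

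The 2 libraries differed by slightly less than independent reads allow. The relative spread was 2.44% below 1, and a share of 0.0007 of 10000 random splits were as low, which argues against chance splitting. Removal of reads at the same position, which would lower the spread more at high counts, could not be decided: the slope was -0.00786 per 10 counts (95% interval -0.0171 to 0.00204). A small share of reads counted in both tables may have the same effect and was not tested. The difference between the libraries at one row was unrelated to that at the next (correlation -0.00104, 95% range of shuffles -0.0109 to 0.0101).

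The 9 regions above 200 summed counts had no intermediate neighbours between 159 and 245. A fault in 1 library is argued against, because 51.4% of their counts came from replicate 1 (Wilson 95% interval 49.8 to 53.0%), against 51.7% in all other regions. Amplification within each library that gives 2 counts for every molecule is argued against as well. The relative spread would then be 2, and it was 0.422 (0.200 to 1.41). Amplified copies of only some molecules were not tested and stay open, since this interval reaches above 1. Whether they are the upper end of the ordinary regions cannot be told apart from a separate class: a negative binomial fitted to the other regions expected 6.82e-09 of them, but it also expected 59.0 regions above 60 counts where 117 were seen, so its upper end is too thin to decide. Long regions, or sequence repeated in the genome, may also give such counts and were not tested.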
